A study of Mus musculus with 10 samples.

How the data were processed

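The series holds 10 libraries, 1 from each of 10 mouse pancreatic cancer cell lines, with the genotype taken from the labels (5 KPC and 5 KPCAf/f). Per the labels' protocols, the lines were grown in DMEM with fetal bovine serum, RNA was isolated with the RNeasy Mini kit, and stranded mRNA libraries were made with an Illumina TruSeq kit. Per the submitters' processing notes, the tools were bcl2fastq 1.8.4, Trimmomatic 0.36, STAR 2.5.2b, featureCounts (Subread 1.5.0p3) and DESeq2 1.14.1 in R 3.3.2. These notes name the builds GRCm38.p5 and mm9 with no role for either, and the counting annotation and its strand setting are not given in the sources used here, so that reads of overlapping and antisense genes are treated as uncertain. Coordinates and transcript lengths printed here come from GENCODE M21 (GRCm38), which holds 47240 (95.3%) of the 49568 gene symbols in the table.

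The deposited values are a signal that is never negative: the authors' gene counts divided by DESeq2 size factors, 1 column per library. All 10 columns matched a line by name, 20856 genes were at 0 in each library, and no symbol was repeated. Dividing out what 1 read is worth in a library gave whole reads within 0.001 read for 100.0% of the values in every library. DESeq2 size factors recomputed from these reads matched those in the deposited values to the 4 decimals compared, from 0.7549 in A1620 to 1.2218 in A1809. The recovered reads per library ranged from 15124888 to 20419830. At this depth 1 read corresponds to about 1 normalized count, and folds against a group with 0 reads are lower bounds against a floor of 3 reads over the group. Intervals for groups with 1 to 3 reads are exact intervals for a ratio of 2 Poisson counts and cover counting error alone. No 2 libraries agreed within sampling noise (lowest chi-square per degree of freedom 60.6), so no library is a copy of another. Each line is counted as 1 replicate, though this check does not show that the lines are independent. The labels give no batch, date or pairing.

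The main test was limma 3.58.1 with an intensity trend in R 4.3.3 on log2(normalized count + 1), two-sided, with Benjamini-Hochberg adjustment over the 13089 genes that had a normalized count of at least 10 in at least 5 of the 10 lines. Arid1a was also compared with an exact permutation test over all 252 splits of the lines. Gene lists of cell types, subtypes and pathways were written from textbook knowledge before the data were examined, as were the design and the first set of other settings. The 27 lists with at least 5 tested genes were tested with camera at its preset correlation of 0.01, and again with an estimated correlation, with fry and with ranks. Reactome pathways of 15 to 300 tested genes came from the mouse collection in fgsea 1.28.0. Genes named in the text follow a rule set beforehand: SWI/SNF subunits, the 12 largest increases and 12 largest decreases among called genes with groups that do not overlap (unnamed, clone-based and pseudogene symbols left out), up to 8 members of each called list and 4 of each other list by smallest p, and sex-linked genes. Some genes and lists are not reported here. Genes named outside it are said to have been looked up afterwards.

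Counts were simulated from the means and library sizes of these lines over 13089 genes. In them 100 genes were changed 4-fold, 100 were changed 16-fold and 40 more were raised 4-fold as a set. Of the 100 and 100 genes, limma recovered 56% and 87% with 5.33% false calls, edgeR 55% and 86% with 4.82%, limma-voom 57% and 84% with 5.39%, and DESeq2 79% and 94% with 26.4%. Calls of the 40 set genes counted as true, and no length-biased or outlying line was simulated. Other settings were 2 other pseudocounts, no filter or a mean of at least 100, quantile and TMM scaling, array weights, edgeR 4.0.16, DESeq2 1.42.0 and limma-voom on the recovered reads, sex-linked genes left out, and each line left out in turn. After the data were seen, autosomal genes alone, a loess correction for transcript length per library, and leaving out A1620 with A1693, or these with A1809, were added. Figures were drawn with matplotlib 3.10.9.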

Results

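Messenger RNA was sequenced from 10 mouse pancreatic cancer cell lines, 5 labelled KPC and 5 labelled KPCAf/f. KPC is the field's name for a mouse model of pancreatic cancer. The labels do not spell out KPCAf/f. The A is read here as Arid1a, the gene in the series title, and f/f as its floxed (conditionally deletable) alleles. The KPC lines were A1081, A1620, A1625, A2031 and A2032, and the KPCAf/f lines were A1693, A1809, A1925, A2441 and A3992. Each line gave 1 library, so that n = 5 lines per genotype. The labels call each line mouse pancreatic cancer cells. KPCAf/f line A1693 had 2.70 normalized counts of Pdx1, a pancreatic homeobox factor, and 10.8 of E-cadherin (Cdh1), so that its values do not show a pancreatic epithelial origin, and counts without it are given below. The labels do not say whether every line came from its own mouse, and p-values therefore measure the spread between these lines. Reads assigned to genes ranged from 15124888 in A2441 to 20419830 in A1809. Values below are counts normalized for library size, given as mean ± SD over the 5 lines of a genotype, and log2 fold changes are KPCAf/f over KPC on the log2(normalized count + 1) scale, which understates the change of low genes. Positive values mean higher in KPCAf/f. Means under 10 rest on few reads, and 1 line can move them by more than 1.5 times. The series title names transformation and epithelial-mesenchymal transition, and the comparison addresses which genes and gene groups differ between lines of the 2 genotypes. Of the genes in the table, 13089 had enough reads to be tested. A gene under 10 normalized counts in every line of 1 genotype was tested only if every line of the other reached 10. Such a gene could differ in 1 direction alone.

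Arid1a, a DNA-binding subunit of the SWI/SNF chromatin remodelling complex, averaged 1465 ± 221 normalized counts in the KPCAf/f lines (n = 5) and 2114 ± 844 in the KPC lines (n = 5). The log2 difference of -0.42 (SE 0.32) did not pass the test (limma adjusted p = 0.563; two-sided exact permutation p = 0.270 over 252 splits, where the smallest possible p is 0.00794). The KPCAf/f lines lay between 1253 (A1809) and 1785 (A1693). KPC lines A1081, A1625, A2031 and A2032 had 2267, 3109, 2460 and 1915, whereas A1620 had 820. A1620 also differed from the other 9 lines in its trend with transcript length. Relative to the mean of all lines, its level fell by 0.65 on the log2 scale per doubling of transcript length across genes. Slopes were -0.02 to 0.04 in the other 4 KPC lines and 0.10 to 0.15 in the 5 KPCAf/f lines. These ranges did not overlap, so leaving out A1620 does not remove a length trend that follows the genotype. The longest annotated Arid1a transcript has 8187 bases. Without A1620 the KPC mean was 2438 ± 501 (n = 4), the log2 difference was -0.72 and the limma adjusted p was 0.0857. The exact permutation p was then 0.00794, the smallest that 126 splits can give. A1620 was the only KPC line below any KPCAf/f line, so leaving it out fixed this p in advance. No conclusion is drawn from that permutation p. Without A1625, the KPC line with the most Arid1a, the log2 difference was -0.24 (limma adjusted p = 0.743). With a correction for transcript length, chosen after the data were seen, the log2 difference was -0.83 and passed the threshold (limma adjusted p = 0.0461). The gene lies on chromosome 4 at 133679008 to 133756769 on the minus strand (GRCm38). Its gene-level count includes exons outside the deleted part, so reads in the KPCAf/f lines do not check whether the allele was recombined.

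**Figure D1:**
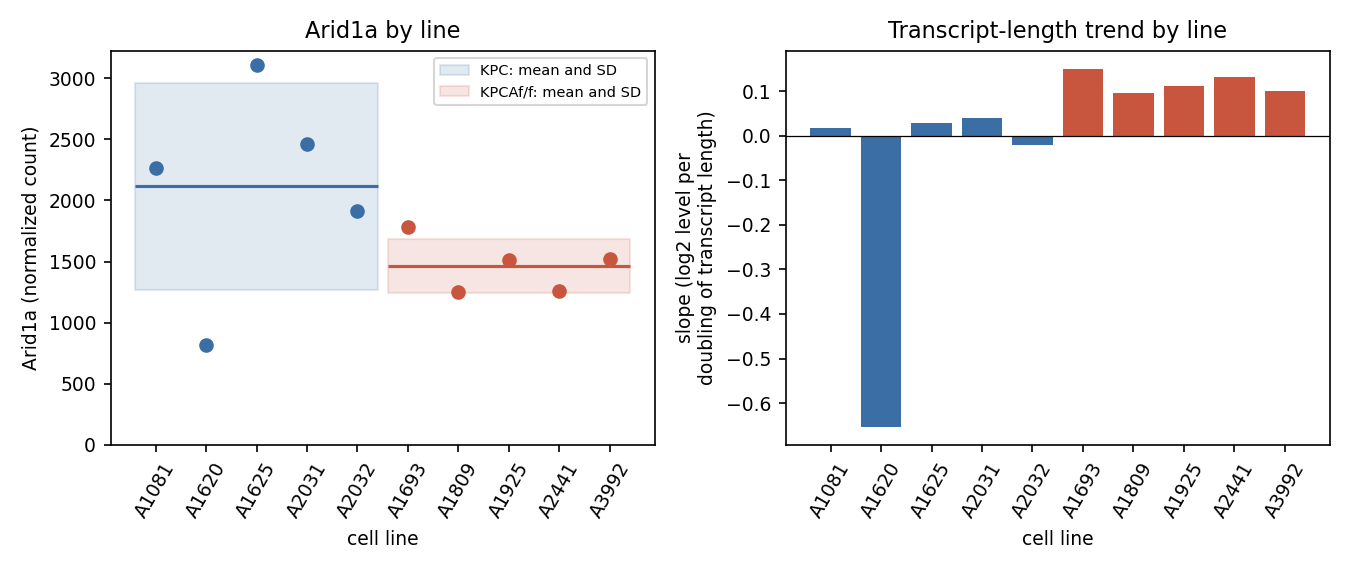
Left, Arid1a in normalized counts per cell line, each point 1 line, with the mean (line) and SD (band) of each genotype. Right, the slope of each line's log2 level on log2 transcript length across genes, as bars from 0. KPC line A1620 has 820 normalized counts of Arid1a and a slope of -0.65. The other KPC lines have slopes from -0.02 to 0.04 and the KPCAf/f lines from 0.10 to 0.15.

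Other SWI/SNF subunits did not differ past the threshold. Of 26 tested members, 0 were called by limma over all genes, 0 adjusted over the list alone, 0 by edgeR, 0 by limma-voom and 1 by DESeq2, and 2 had an unadjusted p under 0.05 (limma camera adjusted p = 0.699; adjusted p = 0.735 with an estimated correlation). Those 2 were Bcl7a, at 182 ± 55.8 normalized counts in KPC and 513 ± 281 in KPCAf/f (limma adjusted p = 0.154), and Smarca2, an ATPase of the complex, at 278 ± 184 and 605 ± 242 (limma adjusted p = 0.280). Smarca4, the alternative ATPase, was at 5961 ± 488 in KPC and 6443 ± 568 in KPCAf/f. Arid1b, the paralog of Arid1a, was at 1048 ± 405 and 1557 ± 299 (log2 fold change 0.68, SE 0.33, limma adjusted p = 0.377), with A1620 at 392.

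The collagen genes Col1a2 and Col3a1, the cross-linking enzyme Lox and the growth factor receptor Pdgfrb were near the detection floor in the KPC lines and rose in the KPCAf/f lines. Col1a2, a chain of type I collagen, rose from 2.36 ± 1.85 normalized counts in KPC to 16366 ± 30761 in KPCAf/f, with KPCAf/f lines between 959 (A2441) and 71336 (A1693) and a KPCAf/f mean of 2623 ± 1614 without A1693 (n = 4). Col3a1, the chain of type III collagen, rose from 1.82 ± 1.76 to 4487 ± 4401 (2665 ± 1923 without A1693), and Lox, which cross-links collagen and elastin, rose from 2.91 ± 3.77 to 1835 ± 962. Pdgfrb, a receptor of mesenchymal cells, rose from 0.667 ± 0.623 to 972 ± 861 (619 ± 398 without A1925), a ratio of 1518 with a counting interval of 519 to 7363. In total 178 genes were higher and 51 lower in KPCAf/f (limma, Benjamini-Hochberg adjusted p under 0.05), and 1917 had an unadjusted p under 0.05.

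The fitted log2 fold changes were 10.50 for Col1a2 (SE 0.98, limma adjusted p = 0.000354), 10.29 for Col3a1 (SE 0.71, adjusted p = 3.95e-05), 9.17 for Lox (SE 0.65, adjusted p = 4.17e-05) and 8.85 for Pdgfrb (SE 0.61, adjusted p = 3.95e-05). Ogn, a small leucine-rich proteoglycan, had 0 reads in the 5 KPC lines and 1232 ± 1991 normalized counts in KPCAf/f (348 ± 268 without A1693), at least 1939-fold higher against a floor of 3 reads over the group. Prrx1, a homeobox factor of limb and craniofacial mesenchyme, rose from 6.84 ± 6.63 to 3295 ± 2953 (2128 ± 1592 without A1693). The others of the 12 genes with the largest increases whose groups did not overlap were Thbs2, Fbn1, Col5a2, Ddr2, Serpinf1 and Mrc2, with log2 fold changes from 7.97 to 8.35. Ddr2 encodes a collagen receptor, Mrc2 a collagen uptake receptor and Fbn1 the microfibril protein fibrillin. Col1a2 lies on chromosome 6 at 4504814 to 4541544, Col3a1 on chromosome 1 at 45311538 to 45349706, Lox on chromosome 18 at 52516067 to 52529867 and Pdgfrb on chromosome 18 at 61045150 to 61085061 (GRCm38). Each of these 12 calls stayed past the limma threshold when any 1 line was left out, with adjusted p of at most 0.00732. With limma-voom 6 of them lost their call, Col1a2 (adjusted p = 0.0992), Ogn (0.0930), Prrx1 (0.0763), Ddr2 (0.128), Serpinf1 (0.0839) and Mrc2 (0.0813).

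**Figure D2:**
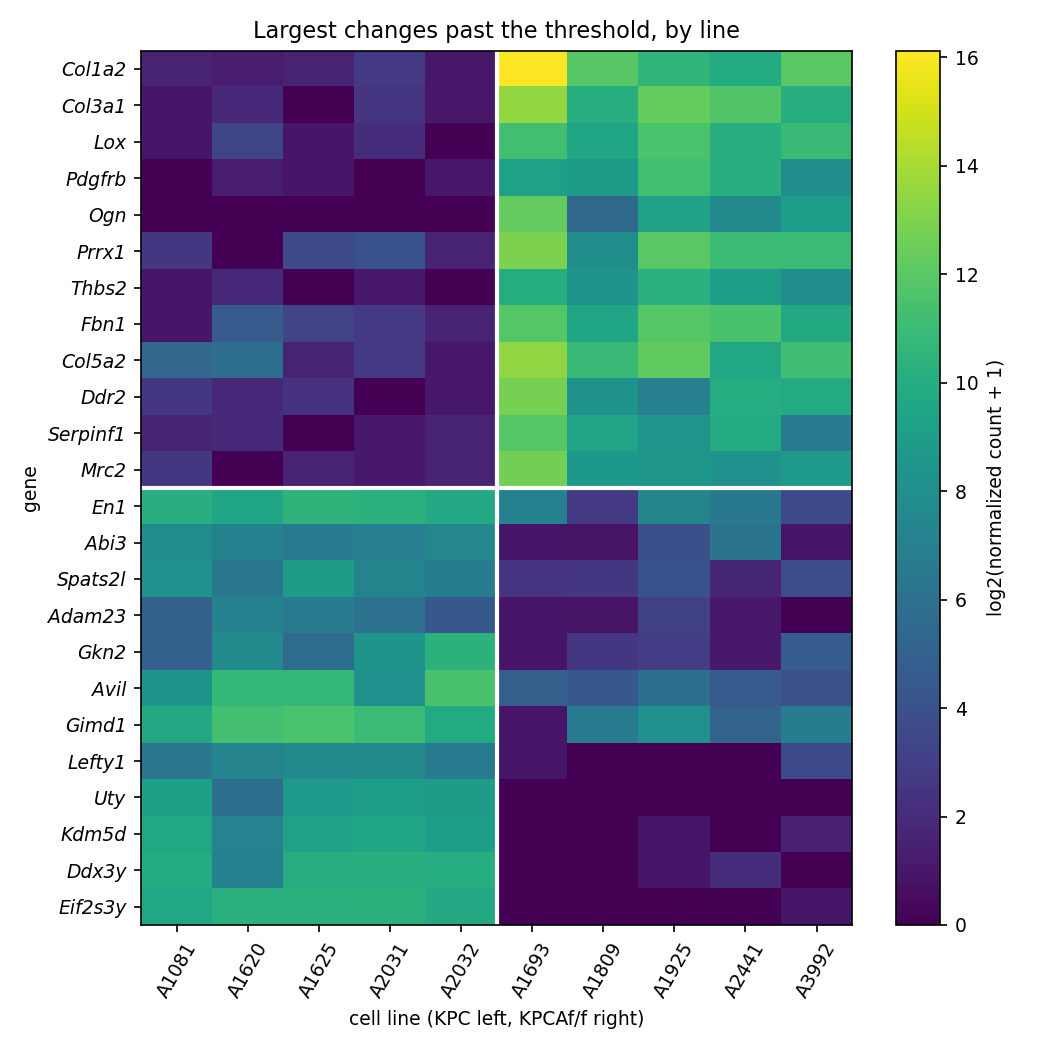
Heatmap of log2(normalized count + 1) for the 12 genes with the largest increases (upper block) and the 12 with the largest decreases (lower block) among genes past the threshold with groups that do not overlap. Columns are the 10 cell lines, KPC left and KPCAf/f right of the white line. Col1a2 has 71336 normalized counts in A1693 and at most 5.59 in a KPC line.

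Genes lower in KPCAf/f were led by the 4 Y-linked genes Eif2s3y, Ddx3y, Kdm5d and Uty, which had between 1148 and 3415 reads together in each KPC line and between 0 and 3 in each KPCAf/f line. Uty had 403 ± 202 normalized counts in KPC and 0 reads in KPCAf/f, at least 777-fold lower against the floor of 3 reads over the group. Eif2s3y had 1079 ± 261 normalized counts in KPC and 1 read in KPCAf/f, a ratio of 5908 with a counting interval of 1060 to 233387. These genes have X-linked paralogs, and reads shared between the copies are not separated here. Xist, transcribed from the inactive X chromosome, had 5278, 15437, 18451 and 12466 normalized counts in the KPCAf/f lines A1809, A1925, A2441 and A3992. KPCAf/f line A1693 had 3.60 and the KPC lines had 1.96 to 6.63. Every gene comparison between the genotypes is therefore also one between lines with and without Y-linked expression.

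Outside the Y chromosome, Lefty1, a secreted antagonist of Nodal, fell from 148 ± 60.6 normalized counts in KPC to 2.47 ± 5.04 in KPCAf/f (0.225 ± 0.450 without A3992; log2 fold change -6.20, SE 0.73, limma adjusted p = 0.00130). Avil, which encodes the actin-binding protein advillin, fell from 1376 ± 1109 to 28.9 ± 16.6 (log2 fold change -5.12, SE 0.68, adjusted p = 0.00284). Gkn2, a secreted gastric epithelial protein, fell from 387 ± 541 (152 ± 137 without A2032) to 7.67 ± 9.83 (3.42 ± 2.88 without A3992; adjusted p = 0.0416). En1, a homeobox factor, fell from 1079 ± 290 to 79.9 ± 70.2 (adjusted p = 0.0193). Gimd1, Adam23, Spats2l and Abi3 completed the 12, with log2 fold changes between -5.17 and -4.60. Lefty1 lies on chromosome 1 at 180935022 to 180938400 and Avil on chromosome 10 at 127000709 to 127020994 (GRCm38). Calls of Gimd1, Gkn2, Abi3 and En1 were lost without at least 1 line, with limma adjusted p up to 0.111, 0.112, 0.100 and 0.0578, while Lefty1, Avil, Adam23 and Spats2l stayed past the threshold. Over all other settings and left-out lines, Gimd1 lost its call in 11, Gkn2 in 14, Abi3 in 14 and En1 in 2 (adjusted p up to 0.111, 0.177, 0.254 and 0.0578). Avil lost its call with limma-voom (adjusted p = 0.0637) and Adam23 without A1620, A1693 and A1809 (adjusted p = 0.0582).

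Among called genes, 159 of the 178 higher ones and 36 of the 51 lower ones changed at least 4-fold, and 118 rose and 23 fell at least 16-fold. The values of the genotypes did not overlap for 593 genes, or 4.53% of those tested, where chance gives 0.794%, and 164 higher and 46 lower called genes were among them. The lower calls numbered 24 to 32 without any 1 KPC line, 30 without A1925 or A2441 and 91 without A1809, against 122 to 227 higher calls when any 1 line was left out. Without A1620 there were 147 higher and 32 lower genes, without A1693 there were 155 and 36, and without A1620 and A1693 there were 141 and 44.

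Mesenchymal genes rose as a group. Of 40 tested members of the 49 in the list, 21 rose and 0 fell over all genes, 26 and 0 adjusted over the list alone, and 19 did not pass over all genes, with 18 higher by edgeR, 23 by DESeq2 and 11 by limma-voom (median log2 fold change 3.75, camera adjusted p = 1.57e-26; adjusted p = 0.0122 with an estimated correlation). Col1a1, the other type I collagen chain, rose from 66.4 ± 48.4 to 9109 ± 5466 normalized counts, and Loxl1, a lysyl oxidase, rose from 5.15 ± 4.95 to 457 ± 314. Cald1, an actin-binding protein of contractile and motile cells, rose from 1782 ± 782 to 13718 ± 4253 (log2 fold change 2.99, SE 0.30, limma adjusted p = 0.000546). Genes of the fibroblast list, fixed as markers of another cell type that tumour-derived cultures can hold, also rose. Of 13 tested members of the 25 in this list, 7 rose and 0 fell over all genes and 10 rose adjusted over the list alone, with 7 higher by edgeR, 8 by DESeq2 and 4 by limma-voom (median log2 fold change 5.34, camera adjusted p = 1.03e-16; adjusted p = 0.000454 with an estimated correlation). Members under 10 normalized counts in every KPC line were tested only if every KPCAf/f line reached 10. The counts and the median of both lists therefore partly reflect the filter. Dcn, at 2.46 in A1809, did not pass it. Neither did Lum, which had 126 normalized counts in A1693 and 0.843 to 7.05 in the other KPCAf/f lines. Over the other settings the fibroblast median ran from 2.82 to 6.52. The fibroblast list shares 5 tested genes with the mesenchymal list. Pdgfra rose from 24.2 ± 19.4 to 1641 ± 1471 (1077 ± 873 without A1925), and Mfap5, a microfibril protein, from 0.265 ± 0.592 to 37.3 ± 23.5, a ratio of 169 with a counting interval of 29.9 to 6695. Pdgfra lost its call with limma-voom (adjusted p = 0.0834). Vim, a filament protein of mesenchymal cells that was looked up after the other values were seen, was at 44690 ± 20643 in KPC and 45689 ± 31439 in KPCAf/f.

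Transcription factors of epithelial-mesenchymal transition rose in part. Of 16 tested, 3 rose and 0 fell over all genes, and 6 rose adjusted over the list alone, with 3 higher by edgeR, 7 by DESeq2 and 1 by limma-voom (median log2 fold change 1.41, camera adjusted p = 5.62e-05; adjusted p = 0.417 with an estimated correlation). They were Prrx1, Snai1, a repressor of E-cadherin, from 3.96 ± 4.0 (2.35 ± 2.01 without A1081) to 247 ± 188 (log2 fold change 5.40, SE 0.82, limma adjusted p = 0.00607), and Foxc2, from 1 read over the KPC lines to 142 ± 176 (67.3 ± 62.0 without A1693), a ratio of 681 with a counting interval of 122 to 26914. Zeb2, another E-cadherin repressor, was at 44.3 ± 34.3 in KPC and 761 ± 702 in KPCAf/f (limma adjusted p = 0.115), and Twist2 at 12.8 ± 16 (8.23 ± 14.1 without A1625) and 308 ± 320 (adjusted p = 0.207). The list shares 7 tested genes with the mesenchymal list. Among TGF-beta response genes, 4 of 33 rose and 1 fell, and 9 and 1 adjusted over the list alone, with 3 and 1 by edgeR, 8 and 1 by DESeq2 and 2 and 0 by limma-voom (median log2 fold change 0.38, and 0.57 without A1693, camera adjusted p = 0.00107; adjusted p = 0.417 with an estimated correlation). Ltbp2, which binds microfibrils, rose from 33.8 ± 17.2 to 1681 ± 795. Tgfbi, a matrix protein induced by TGF-beta, rose from 2.07 ± 1.79 to 475 ± 459 (279.98 ± 166 without A1925), and the ligand Tgfb3 rose from 248 ± 69.4 to 1247 ± 481. Fst, an activin antagonist, rose from 118 ± 151 (51.4 ± 32.3 without A1081, whose 382 lay within the KPCAf/f range) to 698 ± 338 and Id2, an inhibitor of helix-loop-helix factors, fell from 3906 ± 756 to 1559 ± 570. The calls of Fst and Id2 were lost without at least 1 line, with limma adjusted p up to 0.104 and 0.0793, and over all other settings in 12 and 10 (adjusted p up to 0.153 and 0.0830). With limma-voom Snai1 (adjusted p = 0.0909), Prrx1 (0.0763) and Tgfbi (0.0791) lost theirs.

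**Figure D3:**
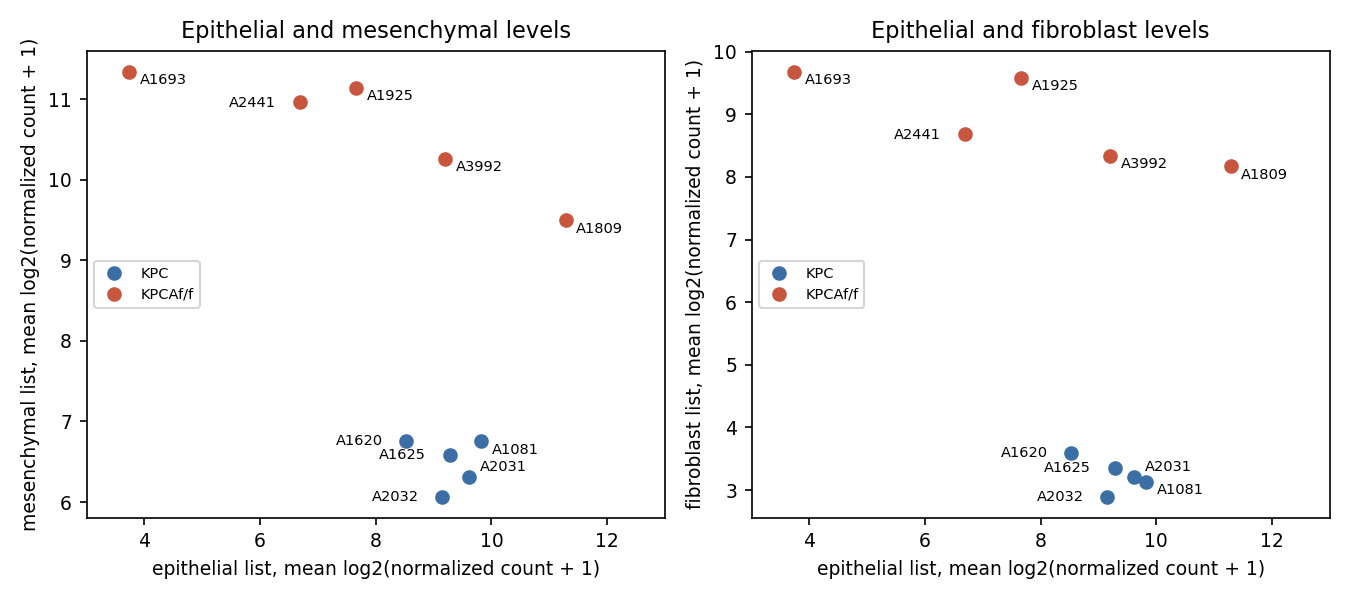
Mean log2(normalized count + 1) of the tested genes of the epithelial list (horizontal axis) against that of the mesenchymal list (left) and the fibroblast list (right), each point 1 cell line. KPC lines lie between 6.07 and 6.76 on the mesenchymal axis and KPCAf/f lines between 9.50 and 11.34, while on the epithelial axis KPCAf/f lines range from 3.74 (A1693) to 11.28 (A1809).

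Epithelial genes varied widely among the KPCAf/f lines. Of 43 tested junction and keratin genes, 0 passed over all genes by limma and 0 adjusted over the list alone, 0 passed by edgeR or limma-voom and 2 fell by DESeq2, and 9 lower and 0 higher had an unadjusted p under 0.05. As a group they were lower (median log2 fold change -1.72, and -0.81 without A1693 or -2.63 without A1809, camera adjusted p = 5.46e-06; adjusted p = 0.516 with an estimated correlation), and the camera test on edgeR statistics did not pass (adjusted p = 0.322). Muc1, a membrane mucin, was at 10697 ± 3090 normalized counts in KPC and 1486 ± 1857 in KPCAf/f (681 ± 527 without A1809; limma adjusted p = 0.121). Krt19, a duct keratin, was at 44034 ± 17533 and 11046 ± 11354 (6222 ± 4093 without A3992; adjusted p = 0.153). Mean list levels on the log2 scale were 3.74 in A1693, 6.69 in A2441, 7.66 in A1925, 9.20 in A3992 and 11.28 in A1809, against 8.53 to 9.82 in KPC lines. The fibroblast list was at 8.17 in A1809, the KPCAf/f line with the highest epithelial level, and between 2.89 and 3.59 in KPC lines.

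Duct and foregut genes were lower in KPCAf/f. Of 24 pancreatic duct genes, 1 fell and 0 rose over all genes, and 7 fell and 1 rose adjusted over the list alone, with 0 lower by edgeR, 3 by DESeq2 and 1 by limma-voom (median log2 fold change -2.18, and -0.99 without A1693, camera adjusted p = 3.12e-06; adjusted p = 0.417 with an estimated correlation). Nr1h4, the bile acid receptor FXR, fell from 106 ± 20.6 to 22.6 ± 18.4 (14.7 ± 6.35 without A2441; log2 fold change -2.44, SE 0.48, limma adjusted p = 0.0283), and up to 0.0787 with 1 line left out and 0.115 over all other settings, with the call lost in 10. Hes1, a Notch target, was at 1061 ± 102 in KPC and 546 ± 204 in KPCAf/f (adjusted p = 0.0814). Spp1, which encodes osteopontin, went against the list, at 42591 ± 34483 and 117249 ± 61502 (adjusted p = 0.208). Of 32 foregut and classical subtype genes, 2 fell and 0 rose, and 4 and 0 adjusted over the list alone, with 0 by edgeR or limma-voom and 4 lower by DESeq2 (median log2 fold change -2.46, and -1.47 without A1693, camera adjusted p = 9.60e-08; adjusted p = 0.460 with an estimated correlation). They were Gkn2 and the gastric mucin Muc5ac, from 206 ± 116 to 21.4 ± 43.2 (2.10 ± 2.01 without A3992; adjusted p = 0.0438, and up to 0.115 with 1 line left out). Over all other settings Gkn2 lost its call in 14 and Muc5ac in 16, the latter with edgeR (adjusted p = 0.286), limma-voom and DESeq2 among them. Of 16 squamous and basal-like genes, 0 passed over all genes by limma, edgeR or limma-voom and 1 fell by DESeq2. With an unadjusted p under 0.05 there were 5 lower and 1 higher, and adjusted over the list alone 2 lower and 1 higher (median log2 fold change -1.34, camera adjusted p = 0.0101; adjusted p = 0.479 with an estimated correlation). That call was lost without A1081 (adjusted p = 0.0587) or A1693 (median -0.81, adjusted p = 0.0515), and with edgeR (adjusted p = 0.124) and DESeq2 (adjusted p = 0.106).

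Growth and metabolic lists were lower in KPCAf/f by small amounts. Of 25 cholesterol synthesis genes, 0 fell over all genes by limma, edgeR or limma-voom and 4 by DESeq2, 6 adjusted over the list alone and 9 at an unadjusted p under 0.05 (median log2 fold change -0.68, camera adjusted p = 8.27e-08; adjusted p = 0.417 with an estimated correlation). Fdft1, the first committed enzyme of sterol synthesis, was at 3290 ± 515 in KPC and 1845 ± 513 in KPCAf/f (limma adjusted p = 0.0887). Of 38 Myc and ribosome biogenesis genes, 0 passed by limma, edgeR or limma-voom, 2 fell by DESeq2 and 8 were lower at an unadjusted p under 0.05, with 0 adjusted over the list alone (median -0.38, camera adjusted p = 2.66e-06; adjusted p = 0.460 with an estimated correlation). Of 39 oxidative phosphorylation genes, 0 passed by limma, edgeR, limma-voom or DESeq2, or adjusted over the list alone and 3 were lower at an unadjusted p under 0.05 (median -0.44, camera adjusted p = 1.07e-05; adjusted p = 0.516 with an estimated correlation). The length-biased KPC line A1620 had the highest level of both lists, 11.98 against at most 11.61 in the other KPC lines for Myc and ribosome biogenesis and 12.44 against at most 11.17 for oxidative phosphorylation. Without A1620 the medians were -0.26 (camera adjusted p = 0.000129) and -0.11 (adjusted p = 0.0146). Leaving out A1620 does not remove the length trend that separates the genotypes. With the correction for transcript length, oxidative phosphorylation lost its call and Myc and ribosome biogenesis kept it. Of 57 cell cycle genes, 0 passed by these tools or adjusted over the list alone and 6 were lower at an unadjusted p under 0.05 (median -0.20, and -0.13 without A1625 or -0.33 without A2032, camera adjusted p = 0.000612; adjusted p = 0.516 with an estimated correlation). Of 32 NRF2 and glutathione genes, 1 fell and 0 rose, and 6 and 1 adjusted over the list alone, with 1 lower by edgeR and limma-voom and 5 lower and 1 higher by DESeq2 (median -0.56, camera adjusted p = 0.000206; adjusted p = 0.460 with an estimated correlation). It was Gsr, glutathione reductase, from 8850 ± 2266 to 3430 ± 879 (limma adjusted p = 0.0206, and up to 0.0642 with 1 line left out and 0.0918 without A1620, A1693 and A1809).

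Signalling lists rose with few members past the threshold. Log2 fold changes were positive for 19 interferon, 21 YAP and TAZ and 12 Wnt genes, and negative for 8, 7 and 7. Of 27 type I interferon response genes, 1 rose and 1 fell, and 5 and 1 adjusted over the list alone, with 0 by edgeR, 7 and 1 by DESeq2 and 0 and 1 by limma-voom (median log2 fold change 0.47, and 0.30 without A1620, camera adjusted p = 0.0132; adjusted p = 0.460 with an estimated correlation). Ifitm3, a restriction factor of enveloped viruses, rose from 41.9 ± 58.8 (15.95 ± 10.8 without A1081) to 1356 ± 1099, and Oasl1 fell from 1262 ± 385 to 378 ± 182, with limma adjusted p up to 0.104 and 0.0849 when 1 line was left out. Over all other settings their calls were lost in 12 and 9 (adjusted p up to 0.199 and 0.108). The list lost its call without A2031 (adjusted p = 0.0609) or A1693 (adjusted p = 0.0809). Of 28 YAP and TAZ target genes, 1 rose and 0 fell, as by edgeR, DESeq2 and limma-voom, and 2 and 0 adjusted over the list alone (median 0.37, camera adjusted p = 0.0129; adjusted p = 0.460 with an estimated correlation). It was Rbms3, an RNA-binding protein, from 14.6 ± 12.2 (9.55 ± 5.48 without A2031) to 268 ± 122, and the list lost its call without A1809 (median 0.21, adjusted p = 0.109) or A3992 (adjusted p = 0.0738). Of 19 Wnt pathway genes, 2 rose and 0 fell, and 4 and 0 adjusted over the list alone, with 2 higher by edgeR, 4 by DESeq2 and 0 by limma-voom (median 0.40, camera adjusted p = 0.0498; adjusted p = 0.479 with an estimated correlation). They were Sfrp2 and Dkk2, both secreted modulators of Wnt signalling, from 0.636 ± 0.983 to 251 ± 192 and from 5.63 ± 4.93 (3.49 ± 1.32 without A1081) to 855 ± 1029 (431 ± 461 without A1693). With limma-voom both lost their call (adjusted p = 0.0754 and 0.199). The Wnt list lost its call without A1081, A1620, A2032, A1925 or A2441, with adjusted p from 0.0679 to 0.206, and its median ran from 0.01 without A2441 to 0.96 without A1693.

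Lists that did not pass still held called genes. Csf1, the macrophage growth factor, rose from 860 ± 350 to 2794 ± 1216 in the inflammatory list (1 of 30 rose, 0 fell, 1 adjusted over the list alone; camera adjusted p = 0.0568), with limma adjusted p up to 0.0835 when 1 line was left out and 0.0858 over all other settings, with the call lost in 11. The list passed without A1693 (camera adjusted p = 0.00414) or A3992 (adjusted p = 0.0414). The glucose transporter Slc2a3 and the enolase Eno2 rose in the glycolysis and hypoxia list (2 of 40 rose, 0 fell, 3 adjusted over the list alone; camera adjusted p = 0.752). By limma-voom 1 of the 2 was called, and Slc2a3 lost its call in 3 other settings (adjusted p up to 0.101). Rarg, a retinoic acid receptor, and Crabp2, its ligand carrier, rose in the aldehyde dehydrogenase and retinoid list (2 of 28 rose, 0 fell; 2 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.865), and Crabp2 lost its call without A1625, A2031 or A2032 (limma adjusted p up to 0.0566) and with limma-voom (adjusted p = 0.137). Median and mean log2 fold change differed in sign for the glycolysis and hypoxia list (-0.17 and 0.08) and for leukocyte genes (0.12 and -0.26), and camera gave lower for both lists. Eda2r rose in the p53 target list (1 of 32 rose, 0 fell, 1 adjusted over the list alone; camera adjusted p = 0.811).

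In the remaining lists 0 genes passed over all genes by limma, edgeR or limma-voom. Antigen presentation genes (18 tested) had 2 higher and 2 lower at an unadjusted p under 0.05, 1 higher and 1 lower adjusted over the list alone and 1 of each by DESeq2 (camera adjusted p = 0.749). DNA repair genes (36 tested) had 0 at an unadjusted p under 0.05 (camera adjusted p = 0.551), and genes of the unfolded protein and integrated stress response (29 tested) had 1 (camera adjusted p = 0.146), with 0 by DESeq2 or adjusted over the list alone in both. The stress response list passed without A2031 (camera adjusted p = 0.0164) or A2441 (adjusted p = 0.0497). Leukocyte genes (6 of 33 tested) and endothelial genes (6 of 17 tested), markers of other cell types, had 1 lower gene and 0 genes, respectively, at an unadjusted p under 0.05 and 0 by DESeq2 or adjusted over the list alone (camera adjusted p = 0.816 and 0.893). Acinar and endocrine genes had 2 tested members each, with 0 past the limma, edgeR or limma-voom threshold over all genes. An unadjusted p under 0.05 was reached by 0 acinar and 1 endocrine gene, and the same numbers passed by DESeq2 and adjusted over the list alone.

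**Figure D4:**
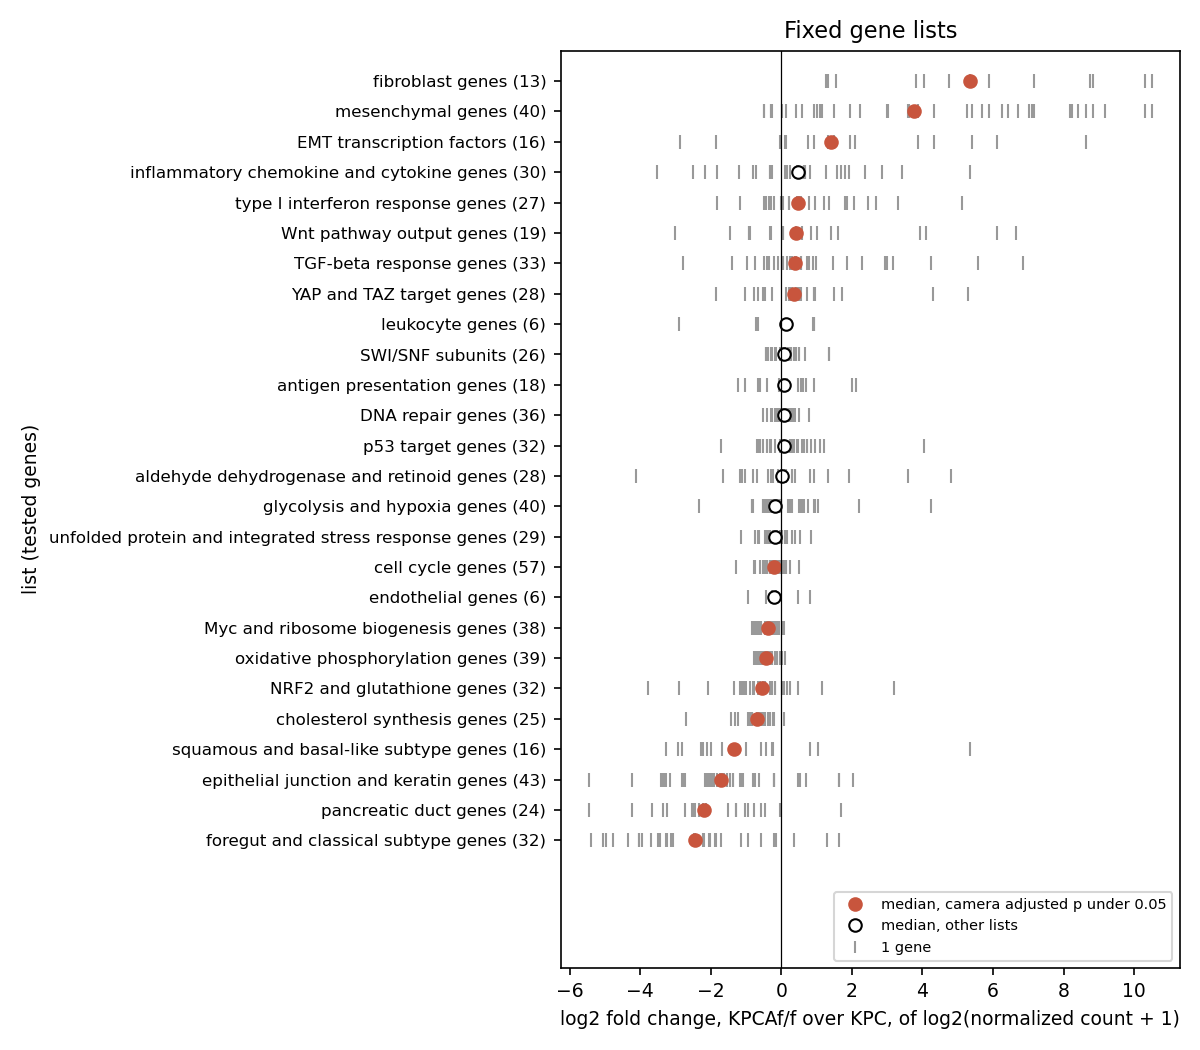
Log2 fold changes, KPCAf/f over KPC, of the tested genes of 26 gene lists (ticks, 1 per gene) and their medians (circles, filled where the camera adjusted p is under 0.05). The fibroblast and mesenchymal medians are 5.34 and 3.75, and the foregut median is -2.46.

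Among 644 Reactome pathways, 141 passed with camera's preset correlation, 25 higher and 116 lower, and 0 passed with an estimated correlation. Of 37 genes of collagen biosynthesis, 10 rose and 0 fell (median log2 fold change 1.44, camera adjusted p = 3.59e-11; adjusted p = 0.186 with an estimated correlation), and of 156 genes of extracellular matrix organization, 29 rose and 0 fell (median 0.53, camera adjusted p = 1.93e-09; adjusted p = 0.186 with an estimated correlation). The lowest p belonged to translation elongation, whose 83 genes held 0 calls by limma (median -0.62, camera adjusted p = 1.43e-11; adjusted p = 0.782 with an estimated correlation). The 77 tested ribosomal protein genes, looked up after this result was seen, had a median of -0.61 and, without the length-biased line A1620, of -0.27. The length trend that separates the genotypes remains without A1620. Without A1620, 52 pathways passed, and with the correction for transcript length 47 did.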

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

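The tests of transcript length and of abundant genes in A1620, of the fibroblast ratios and of the sex chromosomes were chosen after the results they bear on were seen, and the counts over other splits were planned. Across 468 groups of 5 lines, 42 values lay apart from their group by a gap of more than 0.71 of the group's range (a Dixon ratio over the 95% critical value), where chance gives about 23. KPC line A1620 held 21 of them.

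The first pattern is KPC line A1620, whose library was poor in long transcripts. Genes with transcripts under 1000 bases lay a median of 1.46 above the mean of the other KPC lines on the log2 scale (790 genes). A few genes taking most of the reads are argued against, since the share of the 10 most abundant genes was 1.11 percentage points above the highest other KPC line. A loss of long transcripts in this library is a candidate explanation for its low Arid1a, since the deviation of Arid1a (-1.55) was at percentile 34.0 of 1063 genes of similar transcript length, whose central 90% ran from -3.0 to 0.70. No biological explanation was tested, since the design gives none for a single line.

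The values apart in A1620 were, among measures of the whole library, the slope on transcript length (Dixon ratio 0.914), the normalized total (0.945), the share of the 10 most abundant genes (0.793) and the oxidative phosphorylation mean (0.882). Low values in A1620 were Arid2 (0.793), Pbrm1 (0.795), Gltscr1 (0.949), Gltscr1l (0.719), Ddx3y (0.932), Kdm5d (0.743), Uty (0.863), Tead1 (0.894) and Lgr4 (0.834). High values there were Bcl7c (0.773), Krt18 (0.728), Cycs (0.756), Ndufb8 (0.730), Ndufa5 (0.762), Ndufa1 (0.742), Creld2 (0.712) and Mfap5, whose 1 read over the KPC lines was in A1620 (ratio 1). Single reads also set A3992 apart for Eif2s3y and A2031 for Foxc2 (ratio 1 each).

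The second pattern is the rise of collagen and fibroblast genes in the KPCAf/f lines, where 229 genes were called and the highest other split of the 10 lines called 3 (1 of 100 splits as large, the real one), so that a chance split is argued against. Admixed fibroblasts of 1 profile in varying shares are argued against as well, for genes near the detection floor in KPC lines. The SD of log2(gene / Col1a1) among the 5 KPCAf/f lines was taken for 22 called genes of the fibroblast and mesenchymal lists. Its median was 1.66 and its lower quartile 1.48. KPC lines expressed some of these genes, such as Fn1, Cald1 and Itga5 (means 4339, 1782 and 788), whose ratios do not test admixture. The ratio of Col1a2 to Col1a1 ran from 0.0535 to 21.9, the highest in A1693. Without A1693 the log2 ratio ran from -4.22 to -1.04 for Col1a2, -7.62 to -3.42 for Ogn and -5.19 to -0.66 for Prrx1. For Mfap5 it ran only from -8.52 to -7.19. Fibroblasts with a profile of their own in each line cannot be told apart from expression by the tumour cells, because no single cells were measured here and the level of epithelial genes, up to 11.28 in A1809, bounds no admixture. Levels of genes abundant in cultured and tissue fibroblasts were mixed, with Vim at 3198 and Col1a1 at 9533 in A1809, Dcn at most 182 and Lum at most 126 in any KPCAf/f line, and 5 of the 13 fibroblast genes stand in the mesenchymal list too. The genotype and the sex of the lines stay open as biological explanations.

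The third pattern is that sex-linked genes follow the genotype, with Y-linked reads in the 5 KPC lines and in 0 KPCAf/f lines at more than 50 reads. Genes on the sex chromosomes do not make up the calls, since 4.42% of the 226 called genes with a place lay on X or Y (5 on each), and autosomal genes alone gave 173 higher and 43 lower. An effect of sex on autosomal genes cannot be told apart from one of genotype, because 0 KPCAf/f lines had Y-linked expression and each KPC line had it. KPCAf/f line A1693 had 0 Y-linked reads and 3.60 normalized counts of Xist, within the range of the KPC lines.

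Other values apart from their group, with their Dixon ratios, were as follows. Among KPC lines, A1081 was high for Ss18 (0.782), A1625 low for Cd14 (0.711) and high for Fzd7 (0.738), A2031 low for Gsr (0.786), and A2032 low for Mcm3 (0.721), the cell cycle mean (0.846) and the Wnt mean (0.779). Among KPCAf/f lines, A1693 was high for Mrc2 (0.866) and Gapdh (0.823) and low for Jup (0.733). A1809 was low for Brd9 (0.860) and Gbp2 (0.764) and high for Eng (0.803). A2441 was low for Smarcc2 (0.720), Fdps (0.748), Insig1 (0.803) and total reads (0.785), A1925 high for Gstp1 (0.729) and A3992 high for Lefty1 (0.745).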

How the results depend on the processing

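Leaving out 2 or 3 lines, the autosomal genes alone and the length correction were chosen after the data were seen. Under each alternative that gives a value, more genes were higher than lower in KPCAf/f and the fibroblast and mesenchymal lists kept their call (largest adjusted p 0.000454 and 0.0122 over 28 alternatives). The 178 higher genes became 109 at a mean of at least 100, 403 with array weights, 521 with DESeq2 and 76 with limma-voom, and 122 to 227 with 1 line left out. The 51 lower genes became 22, 183, 210 and 29 under the same settings, 27 with edgeR (145 higher; 100% of values were whole reads), 95 without A1620, A1693 and A1809, and 24 to 91 with 1 line left out. Fewer genes were tested at a mean of at least 100 (10572). DESeq2 had the highest false-call share on simulated data (26.4%), where each gene started from its mean over all lines. Whether that share explains its higher counts, and what caused the other shifts, was not tested. Of the 229 calls, edgeR kept 166, DESeq2 222 and limma-voom 103. The 16 lists past the threshold became 2 with an estimated correlation and 4 with fry, and 13 to 19 elsewhere. The 141 Reactome pathways became 212 without a filter, 58 with quantile scaling, 0 with an estimated correlation, 47 with the length correction, 89 without A1620 and A1693, 55 without A1809 as well, and 52 (without A1620) to 190 with 1 line left out. The log2 difference of Arid1a kept its sign, from -0.83 with the length correction, where it passed (adjusted p = 0.0461; adjusted p 0.0516 to 0.743 elsewhere), to -0.24 without A1625. Among named genes 4756 results over all alternatives kept their side of the threshold, 100 passed newly and 150 no longer passed, and among lists 684, 14 and 56. Of 51 called named genes, 38 stayed past it without any 1 line. Calls of lists were also lost as follows, with adjusted p. Epithelial genes lost theirs with edgeR (0.322) and DESeq2 (0.315), and squamous genes with edgeR (0.124) and DESeq2 (0.106). With the length correction it was oxidative phosphorylation (0.128), YAP and TAZ targets (0.0735) and Wnt genes (0.0721), and with quantile scaling cell cycle (0.0558), interferon (0.0656) and Wnt genes (0.0545). Wnt genes lost theirs with a pseudocount of 0.5 (0.0524), limma-voom (0.158) and ranks (0.209) as well, and interferon genes at a mean of at least 100 (0.0802) and without A1620 and A1693 (0.138). Without A1620, A1693 and A1809 it was interferon (0.103), oxidative phosphorylation (0.115), NRF2 (0.0641) and YAP and TAZ targets (0.0570). The inflammatory list gained a call in 11 alternatives and the stress response list in 3. A planned covariate for Y-linked expression could not be fitted, because it does not vary within a genotype. No paired analysis was possible because the labels give no shared replicate numbers. Depth limits low genes, and 1 read in the KPC lines left the ratio of Foxc2 between 122 and 26914.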

Other observations

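Genes in this part were chosen after their values were seen, the flanking region was tested with a bound set beforehand, and the list of imprinted genes was written after the data were examined. Members of 3 matrix gene families, some of them in the mesenchymal and fibroblast lists, rose in KPCAf/f and 0 fell. Of 24 tested collagen chains 9 rose and 0 fell (median log2 fold change 2.36), of 10 Adamts proteases 4 rose and 0 fell (Adamts1, Adamts2, Adamts5 and Adamts14), and of 5 lysyl oxidases 3 rose and 0 fell (Lox, Loxl1 and Loxl3). Among abundant genes, fibronectin (Fn1) rose from 4339 ± 1882 to 37427 ± 19286 normalized counts (limma adjusted p = 0.00731) and thrombospondin 1 (Thbs1) from 985 ± 804 to 18085 ± 15577 (11485 ± 5759 without A1809; adjusted p = 0.0104). Grem1, a secreted BMP antagonist, rose from 34.2 ± 42.6 (15.6 ± 10.9 without A1625) to 12155 ± 14806 (7423 ± 11961 without A2441; adjusted p = 0.00630), and Slit2, a guidance ligand, from 42.1 ± 23.1 to 2439 ± 1746 (adjusted p = 0.00130). In the other direction aggrecan (Acan), a cartilage proteoglycan, fell from 6354 ± 2408 to 859 ± 946 (539 ± 714 without A1809; adjusted p = 0.0310), the protein C receptor Procr from 2420 ± 1045 to 450.4 ± 226 (adjusted p = 0.0158) and Klf4, a factor of epithelial differentiation, from 2868 ± 982 to 986 ± 329 (adjusted p = 0.0275). Nr0b2, the corepressor SHP that FXR induces, fell from 123 ± 118 (73.0 ± 40.5 without A2032) to 8.11 ± 17.6 (0.225 ± 0.450 without A3992; adjusted p = 0.0328). A3992 had 39.6 normalized counts of it, so that the genotypes overlapped.

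Single lines differed in identity genes. KPCAf/f line A1693 had 2.70 normalized counts of Pdx1, the pancreatic homeobox factor, where the other 9 lines had 593.6 to 1679, and 10.8 of Cdh1 (E-cadherin), where they had 3143 to 22853. A1809 had the highest Epcam (6720, others 15.3 to 754) and the lowest Vim (3198, others 31729 to 86632). Cldn18, a claudin of gastric epithelium, was at 15860, 9945, 3379 and 8612 in A2031, A2032, A1809 and A2441 and at most 41.7 in the other 6 lines, which crosses the genotypes. Trp53 was at 771 in A3992 and at 97.9 to 174 in the other 9 lines. Grb10, an imprinted adaptor gene, was at 3141, 2500 and 3175 in A1693, A1925 and A3992, at 9.82 and 1.12 in A1809 and A2441, and at most 28.4 in KPC lines.

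A hypothesis that genes carried along with the floxed allele differ was tested within 20 Mb of Arid1a on chromosome 4. There 2 of 391 tested genes were called (0.512%; Artn and Nr0b2), against 224 of 12388 elsewhere (1.81%). A one-sided Fisher exact test gave p = 0.993, which argues against an excess of called genes in the window. Changes of carried genes too small to be called are not covered by this test.

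A second hypothesis was that imprinted genes differ as a group. Of 12 tested, 1 rose and 0 fell. It was H19, at 0 to 5.68 normalized counts in KPC lines and 21.4 to 393 in KPCAf/f lines (limma adjusted p = 0.00591). The mixed test of fry, for change in either direction, gave p = 1.27e-06 for the list, and in a permutation of gene names 12 of 200 random lists of 12 genes had a p as low. A mixed p under 0.05 was reached by 91 of the 200. A low mixed p is therefore common for random lists, and no difference of imprinted genes as a group is concluded from it. Phlda2 was at 304 ± 118 in KPC and 49.5 ± 51.9 in KPCAf/f (27.95 ± 22.1 without A1809; limma adjusted p = 0.0531), and Igf2r at 1302 ± 1065 and 3749 ± 1999 (adjusted p = 0.157).

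Counts of gene sets gave less separation from other splits of the 10 lines than counts of genes. The real split had 16 lists past the threshold and the highest other split also 16, with 2 of 100 splits as large, the real one included. A chance split is argued against at that share for the total count alone. The other splits had from 2 to 16 lists, and many of them had 9 to 15 lists with 0 called genes. The total therefore does not show which of the 16 lists exceed chance. In the real split 2 lists passed with an estimated correlation and 4 with fry. For Reactome pathways the real split had 141 and the highest other split 294, with 34 of 100 splits as large, so that chance is not excluded for that count. The splits with 294 pathways called 0 genes, and with an estimated correlation 0 pathways passed in the real split. Whether a structure of the lines or camera's preset correlation gives such counts was not tested.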
